A study of Homo sapiens with 6 samples.

How the data were processed

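RNA of BE(2)-C cells, an established human neuroblastoma line with amplified MYCN, was measured on Affymetrix gene-level arrays, 1 array per sample. The 6 samples were 3 treated with 5 µM BIX01294 for 24 h and 3 that received 0.05% DMSO, the solvent, for 24 h. No DMSO content is recorded for the treated samples. The series design text calls the 3 samples of each treatment independent. The labels' protocols state that total RNA was extracted with Trizol and labelled with a terminal labelling kit.

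Per the labels, the deposited table holds 1 expression value per transcript cluster and array, and the values are on a log2 scale, as read from the values themselves: they run from 1.93 to 14.93 with array medians of 6.94 to 7.01. Partek is the only tool that the submitters' processing notes name; the background correction, the normalization between arrays and the summarization over probes are not given in the sources used here. Whether the arrays were brought to a common scale before deposit is not stated. Their medians lie close together, and if they were scaled to each other a shift shared by most genes would not be seen. The table gives no detection call, so no gene was called absent, levels near background were not told apart from it, and the number of arrays limits the precision.

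Of 32321 rows, 19158 had exactly 1 gene symbol in the platform annotation, 1388 had several and 11775 had none in the table used. Entrez identifiers of 19128 of the single-symbol rows matched the RefSeq gene table of assembly GRCh38.p14, which was used for names and for chromosome membership only. Where a gene had several rows (637 of 18404 genes), the row with the highest mean over the 6 arrays was kept. Rows with several symbols or none were left out of the main test. All 6 value columns were used.

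The values were tested as deposited with limma 3.58.1 in R 4.3.3: a linear model with treatment as its only term, moderated by empirical Bayes, two-sided, with Benjamini-Hochberg adjustment over the 18404 genes and a threshold of 0.05. No filter on dim genes was applied. Adjusted p-values below are from this fit unless another test is named, and each log2 change is BIX01294 minus DMSO with its standard error. Replicates were compared before they were averaged: the median absolute difference between arrays of a group was 0.083 to 0.116 on the log2 scale, and 23 to 40 of the 32321 rows held identical values. The fit was also run on 20 simulated data sets with the real means and spreads of the 18404 genes and 200 changed genes each. It recovered 68.5% of genes changed by 0.5 on the log2 scale, 95.7% changed by 1 and 99.9% changed by 2. Of its calls, 4.45% were false. The simulated noise was independent between genes, and 4349 genes were called in the real data, so these shares need not hold there.

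Before the data were examined, 23 gene lists (429 entries, 396 of them measured here), the rule for the genes to name and the alternatives were fixed. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 23 lists, with an estimated correlation and limma's fry as alternatives. For each list, members past the threshold over all genes were counted, and also those past it when adjusted over the list alone; the list's median was placed among 10000 random lists matched on mean expression. The genes named are EHMT1 and EHMT2, the 8 largest rises and the 8 largest falls past the threshold with no overlap between the groups (leaving out locus numbers, open reading frame names, small RNAs and replication-dependent histones), all members of the serine and glycine list, and up to 4 members past the threshold in each other list. Where no member of such a list passed, the member with the largest change was to be given as values. ATF4, ASNS, DDIT3, TRIB3 and MYCN, and the genes named only in the closing section, were chosen after their values were seen.

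The alternatives were quantile normalization, centring of each array on its median, 2 filters on dim genes, the mean of all rows of a gene, an intensity trend with robust estimation, array weights, the replicate number as a block, all rows with a symbol, all rows (added after seeing the data), limma's treat with a minimum log2 change of 0.5, and leaving out each array in turn. Both groups carry the numbers 1 to 3, but the labels do not say that a number marks a shared culture or day.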

Results

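BIX01294 is a small-molecule inhibitor of the histone H3 lysine 9 methyltransferases G9A and GLP, encoded by EHMT2 and EHMT1. The arrays address which transcripts differ in BE(2)-C neuroblastoma cells after 24 h in 5 µM BIX01294, compared with 0.05% DMSO, with 3 arrays per group. Array medians lay between 6.94 and 7.01 on the log2 scale, and the mean correlation of an array with its own group (0.997 to 0.998) was above that with the other group (0.991 to 0.992) for all 6 arrays.

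The transcripts of the inhibited enzymes did not pass the test. EHMT2 measured 8.47 ± 0.03 (SD, n = 3) in DMSO and 8.47 ± 0.06 (SD, n = 3) in BIX01294, with a standard error of the difference of 0.057 and an adjusted p of 0.998 in limma. EHMT1 differed by 0.11 ± 0.059 (SE) on the log2 scale, with an adjusted p of 0.226. BIX01294 acts on the enzymes, so these levels do not check the sample labels.

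BIX01294 was followed by changes in 4349 of 18404 genes, 2379 higher and 1970 lower, most of them small: the median absolute log2 change of these genes was 0.33. The balance of directions turned with the scaling: 2256 genes were higher and 2282 lower (49.7% higher) after quantile normalization, and 2762 higher and 1536 lower (64.3% higher) after centring, against 54.7% higher as deposited. A change of at least 2-fold was seen in 110 genes, of which 43 were higher and 67 lower. The largest rises included 3 metallothioneins, which bind zinc and copper: MT1G rose 8.73-fold, from 6.87 ± 0.12 to 9.99 ± 0.10 (SD, n = 3 per group; adjusted p 6.09e-07 in limma), MT2A rose 8.23-fold and MT1F 5.58-fold. FABP3, a fatty acid-binding protein, rose 8.13-fold, and HTN1, which encodes a salivary peptide, rose from 3.66 ± 0.23 to 6.53 ± 0.30 (SD, n = 3 per group). S100A10 rose 4.06-fold, MGP, matrix Gla protein, 3.81-fold, and the tetraspanin TSPAN8 3.21-fold. The largest falls were led by CHAC1, a glutathione-degrading enzyme, from 10.84 ± 0.09 to 7.75 ± 0.11 (SD, n = 3 per group), an 8.49-fold fall with an adjusted p of 6.09e-07 in limma. DDIT4, an inhibitor of mTORC1 signalling, was 8.08-fold lower, the cystine transporter SLC7A11 5.74-fold lower and the secreted glycoprotein STC2 4.36-fold lower. ULBP1, a ligand of the receptor NKG2D, fell 4.12-fold, NELL1 3.51-fold and the stress protein SESN2 3.42-fold, and TCP11L2 fell from 6.55 ± 0.18 to 4.58 ± 0.11 (SD, n = 3 per group). The lower levels of HTN1 and TCP11L2 lay under the lower quartile of every array and were not shown to be above background, so no fold is given for them, and the filters on dim genes left both out. All 16 of these genes kept their direction and their call in every alternative that tested them, but MT1 and MT2A transcripts come from closely related genes whose probes can share targets, and a second row of MT2A rose by 1.55 against 3.04 for the row used. The groups did not overlap in 4345 of the 4349 changed genes and in 40.1% of all genes, where chance gives 10%.

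**Figure D1:**
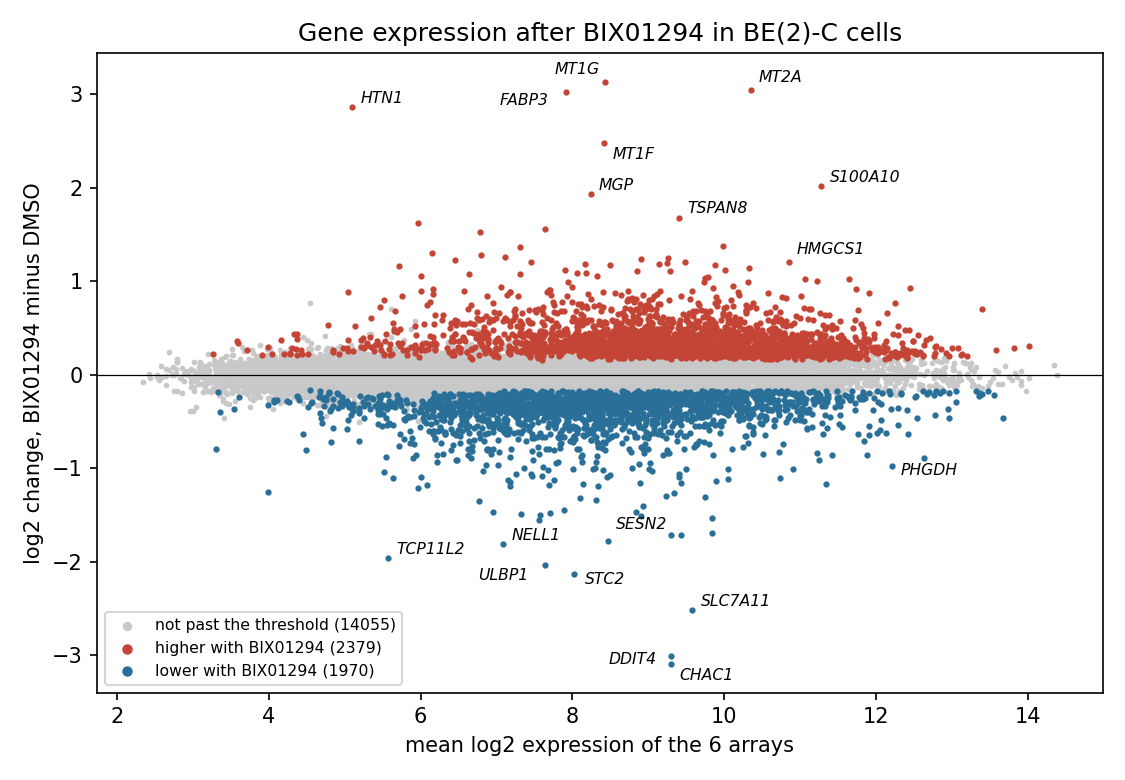
Each point is 1 of the 18404 genes, with its mean log2 expression over the 6 arrays on the horizontal axis and its log2 change (BIX01294 minus DMSO) on the vertical axis; colours mark genes past an adjusted p of 0.05, with counts in the legend. The labelled genes are the 8 largest rises, the 8 largest falls, PHGDH and HMGCS1.

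Genes of serine and glycine synthesis fell. Of the 5 members measured, 4 fell and none rose, over all genes and also adjusted over the list alone. PHGDH, the first enzyme of serine synthesis from glucose, fell 1.97-fold, from 12.70 ± 0.04 to 11.72 ± 0.01 (SD, n = 3 per group). PSAT1, the second enzyme, fell 1.88-fold, PSPH, the third, 1.77-fold, and SHMT2, which makes glycine from serine in mitochondria, 1.81-fold; the highest adjusted p among these 4 in limma was 0.000359, that of PSPH, whose second row fell by 0.73. The cytosolic enzyme SHMT1 differed by 0.06 ± 0.058 (SE), with an adjusted p of 0.558. The list passed camera (adjusted p = 0.000102; adjusted p = 0.172 with an estimated correlation). It was written with knowledge of the study of this treatment, so its count is not independent evidence of its direction. In the related list of folate one-carbon metabolism, 4 of 12 measured members fell and 3 rose, with 4 and 5 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.879). The mitochondrial enzymes ALDH1L2 and MTHFD2 fell 2.41-fold and 1.54-fold, while thymidylate synthase (TYMS) rose 1.41-fold and the mitochondrial folate carrier SLC25A32 rose 1.29-fold. The folate list's median was 0.08 and its mean -0.06, and without DMSO replicate 1 or BIX01294 replicate 3 only 2 members fell.

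**Figure D2:**
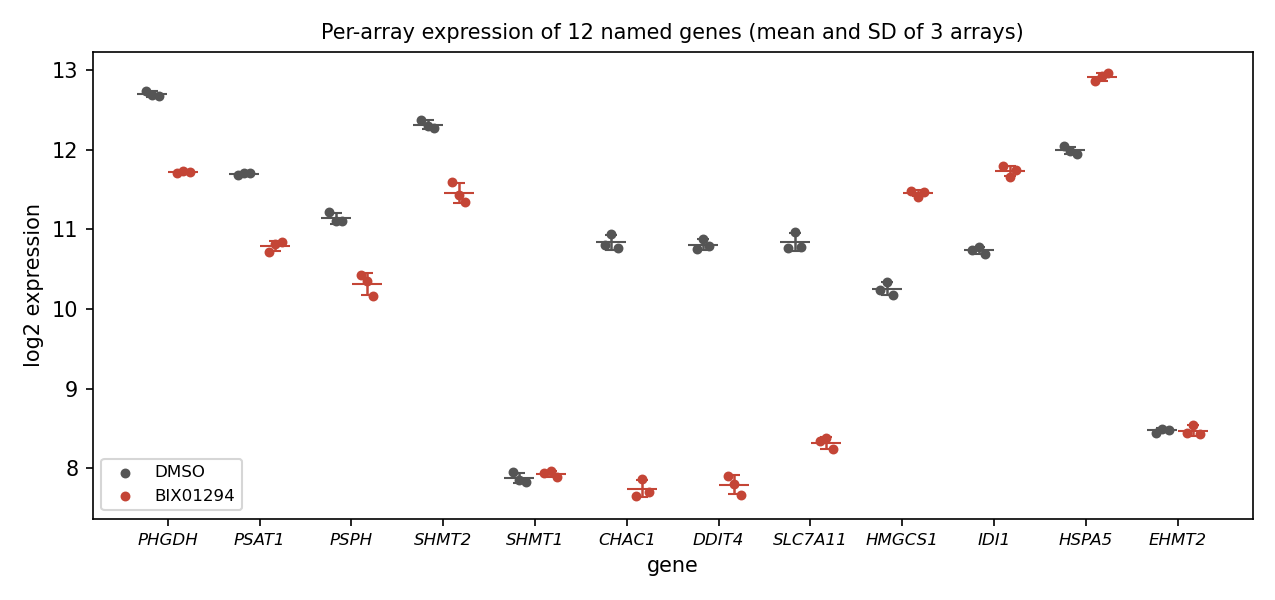
Log2 expression (vertical axis) of 12 named genes in each of the 3 DMSO and 3 BIX01294 arrays, with bars for the mean and SD of each group. PHGDH, PSAT1, PSPH, SHMT2, CHAC1, DDIT4 and SLC7A11 lie lower in all 3 BIX01294 arrays, HMGCS1, IDI1 and HSPA5 higher, and SHMT1 and EHMT2 did not pass the test.

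The ATF4-linked stress response list had the largest shift of the 23 lists. ATF4 is the transcription factor of the integrated stress response, and 16 of the 18 listed genes fell, none rose and 2 did not pass the test; adjusted over the list alone, 17 fell. The median of the list was -1.47, below that of all 10000 random lists matched on expression, whose central 95% ran from -0.10 to 0.13. Besides CHAC1, DDIT4, STC2 and SESN2, the falls included asparagine synthetase (ASNS, -1.69 ± 0.058 SE), the transcription factor DDIT3 (-1.53 ± 0.081 SE) and the pseudokinase TRIB3 (-1.51 ± 0.063 SE), which were chosen after their values were seen. ATF4 itself has 2 rows that disagree: the brighter fell by 0.52 on the log2 scale, and the other differed by 0.10 and did not pass the test. The list passed camera (adjusted p = 4.25e-18; adjusted p = 0.142 with an estimated correlation).

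Amino acid transporters and cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were also lower. Of 12 transporters measured, 8 fell and 1 rose, and 11 fell adjusted over the list alone. After SLC7A11 the largest falls were those of the glycine transporter SLC6A9 (2.02-fold), the neutral amino acid transporter SLC1A4 (1.99-fold) and SLC7A5, a transporter of leucine and other large neutral amino acids (1.79-fold, adjusted p 3.76e-05 in limma). Of 19 synthetases measured, 12 fell and 3 rose, with the same counts over the list alone, and CARS1 fell 2.10-fold, AARS1 and GARS1 1.56-fold each and SARS1 fell by 0.59 on the log2 scale. The transporters passed camera (adjusted p = 1.38e-07; adjusted p = 0.163 with an estimated correlation), as did the synthetases (adjusted p = 9.52e-05; adjusted p = 0.318 with an estimated correlation).

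Genes of cholesterol synthesis and uptake rose. Of 19 measured members of a list of 25, 15 rose and none fell (the other listed genes were not analysed here), with the same counts over the list alone, and the median of 0.70 lay above that of all 10000 matched random lists. HMGCS1, which makes HMG-CoA for the mevalonate pathway, rose 2.30-fold, from 10.25 ± 0.08 to 11.45 ± 0.03 (SD, n = 3 per group; adjusted p 2.30e-05 in limma). The sterol demethylation enzyme MSMO1 rose 2.03-fold, the isoprenoid enzyme IDI1 2.00-fold and ACAT2, an acetoacetyl-CoA-forming thiolase, 1.99-fold. The list passed camera (adjusted p = 3.41e-12; adjusted p = 0.163 with an estimated correlation). In fatty acid synthesis, 4 of 11 measured members rose and 1 fell, with 6 and 1 over the list alone. Acetyl-CoA synthetase ACSS2 rose 1.52-fold, malic enzyme ME1 and the elongase ELOVL6 1.35-fold each, while the transcription factor SREBF1 fell 1.27-fold. The fatty acid list passed camera (adjusted p = 0.00518; adjusted p = 0.454 with an estimated correlation), and its call was lost when genes below the median level were left out (adjusted p = 0.07355; 0.000906 to 0.454 over its alternatives). Its median of 0.17 lay at percentile 93.77 of matched random lists, inside their central 95% of -0.10 to 0.20.

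Chaperones of the endoplasmic reticulum rose while a stress gene on the same list fell. Of 16 members measured, 12 rose and 2 fell, with the same counts over the list alone. HSPA5, the main chaperone of this compartment, rose 1.90-fold (adjusted p 4.21e-05 in limma), and the co-chaperones DNAJB11 and DNAJC3 rose 1.83-fold and 1.76-fold. HERPUD1, which takes part in the degradation of misfolded proteins, fell 2.02-fold. The list passed camera (adjusted p = 1.38e-05; adjusted p = 0.211 with an estimated correlation).

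Genes of DNA replication and ribosome biogenesis rose modestly. Of 23 replication genes, 16 rose and none fell, and 18 rose adjusted over the list alone. Cyclin E2 (CCNE2) rose 2.16-fold, the flap endonuclease FEN1 1.60-fold, and the origin licensing factor CDC6 1.54-fold, and the replication factor MCM10 rose by 0.58 on the log2 scale. Replication passed camera (adjusted p = 9.57e-10; adjusted p = 0.211 with an estimated correlation). Of 21 mitosis genes, 6 rose and none fell, over all genes and over the list alone, and the list did not pass (adjusted p = 0.0955). CDK1 rose 1.26-fold, and CDC20, CCNB1 and KIF23 rose 1.22-fold, 1.22-fold and 1.21-fold. The count of rising mitosis genes was 2 without DMSO replicate 1 and 3 without BIX01294 replicate 3, CCNB1 lost its call without DMSO replicate 1, and KIF23 without DMSO replicate 1 or BIX01294 replicate 2 or 3. Without BIX01294 replicate 2 the mitosis list passed (adjusted p = 0.0289). Of 18 ribosome biogenesis genes, 11 rose and none fell, with 12 and 1 over the list alone, and 7 rose without BIX01294 replicate 1. RRS1 rose 1.90-fold, NOP2 1.58-fold, NOP16 1.36-fold and UTP20 1.33-fold, and the list passed camera (adjusted p = 4.78e-06; adjusted p = 0.374 with an estimated correlation).

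Genes of neuronal differentiation moved in both directions, with more rises: 9 of 19 rose and 2 fell, with 10 and 2 over the list alone. The secreted neuropeptide precursor VGF rose 2.04-fold and neurofilament heavy chain NEFH 1.60-fold, whereas the microtubule regulators DCX and STMN2 fell 1.67-fold and 1.37-fold. The list passed camera (adjusted p = 0.000712; adjusted p = 0.266 with an estimated correlation), and its median lay at percentile 98.08 of matched random lists. Among 18 measured genes of MYCN and sympathoadrenal identity, 5 rose and 4 fell, with 5 and 6 adjusted over the list alone, and the list did not pass (adjusted p = 0.914). MYCN, named after its value was seen, differed by -0.08 ± 0.053 (SE) with an adjusted p of 0.343, the vesicular monoamine transporter SLC18A2 rose 1.38-fold, the transcription factors ISL1 and HAND1 rose 1.26-fold and 1.18-fold, and TBX2 fell 1.33-fold. The sympathoadrenal list's median was -0.03 and its mean 0.01, and leaving out any single array lowered its rises to 3 or 4 and its falls to between 1 and 3. Markers of mesenchymal or Schwann cell-like cells, another state that such a culture can hold, did not shift as a list (adjusted p = 0.843): 5 of 22 rose, among them vimentin (VIM, 1.77-fold) and CD44 (1.40-fold), and 3 fell, among them the matrix proteoglycans DCN (2.84-fold) and LUM (1.54-fold), with the same counts over the list alone. The mesenchymal list's median was -0.01 while camera gave a rise.

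NRF2-linked antioxidant genes rose in 7 of 14 measured members and fell in 1, with 7 and 2 over the list alone. The quinone reductase NQO1 rose 2.25-fold, the glutathione synthesis subunit GCLM 1.92-fold and sulfiredoxin SRXN1 1.62-fold, while SLC7A11 was the member that fell. The list passed camera narrowly (adjusted p = 0.0331; adjusted p = 0.680 with an estimated correlation), with its median at percentile 97.52 of matched random lists. That call was lost without DMSO replicate 3 (adjusted p = 0.0537) and without BIX01294 replicate 1 (adjusted p = 0.0875), within a range of 0.0227 to 0.680 over its alternatives, and without BIX01294 replicate 3 only 4 members rose.

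The other lists did not pass camera. Of 22 lysosome genes 7 rose and 2 fell, with 7 and 3 over the list alone (adjusted p = 0.163), among them the cholesterol-binding protein NPC2 (1.54-fold higher), the protease CTSL (1.42-fold), NEU1 (1.37-fold) and GLA (1.33-fold). Leaving out any single array lowered the rising lysosome genes to 5 or 6 and the falling ones to 1 or 0. Of 18 autophagy genes 4 rose and 6 fell, with 6 and 6 over the list alone (adjusted p = 0.675). The cargo receptor SQSTM1 rose 2.06-fold and ATG3 1.37-fold, while the kinase ULK1 fell 1.36-fold and GABARAPL1 1.34-fold. Leaving out any single array lowered the falling autophagy genes to 4, with 3 to 5 rising. Of 14 p53 target genes 1 rose and 2 fell, over all genes and over the list alone (adjusted p = 0.580): TP53I3 rose 1.69-fold, TP53INP1 fell 2.04-fold and SESN1 1.21-fold. In the BCL2 family, 4 of 15 rose and 2 fell, over all genes and over the list alone (adjusted p = 0.914): the pro-apoptotic PMAIP1 and BCL2L11 fell 1.61-fold and 1.58-fold, and the anti-apoptotic MCL1 and BCL2 rose 1.33-fold and 1.30-fold. The family's median was -0.02 while camera gave a rise, and 2 members rose without DMSO replicate 2 or 3 or without BIX01294 replicate 1 or 2.

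Among genes of the H3K9 methylation machinery, 3 of 19 rose and 5 fell, over all genes and over the list alone (adjusted p = 0.482). The demethylase KDM4A fell 2.01-fold and the methyltransferase SETDB1 1.43-fold, while the methyltransferase SUV39H1 rose 1.33-fold. UHRF1 rose 1.38-fold in its brighter row, its second row differed by -0.09 and did not pass, and with the mean of both rows it differed by 0.19 and lost its call (adjusted p = 0.0671 in limma). Without DMSO replicate 1, 3 machinery genes fell. Of 20 germline genes, 1 fell and none rose, and adjusted over the list alone 0 passed (adjusted p = 0.353 in camera). TEX15, a dim gene, fell from 5.40 ± 0.08 to 4.99 ± 0.22 (SD, n = 3 per group). TEX15 lost its call without DMSO replicate 1 or 2 or BIX01294 replicate 1 or 3. Too few germline genes lay above the median expression level for the list to be tested with that filter, so changes in this list could be missed. Of 18 interferon response genes 3 rose and 3 fell, over all genes and over the list alone (adjusted p = 0.674): OAS1 and OAS3 rose 1.74-fold and 1.44-fold, IFI6 fell 1.22-fold, and IFIT1, a dim gene, fell by 0.30 on the log2 scale. IFIT1 lost its call without DMSO replicate 2 or 3 or BIX01294 replicate 1 or 2. Of 23 genes of glycolysis and the hypoxia response 5 rose and 3 fell, with 7 and 3 over the list alone (adjusted p = 0.427): VEGFA fell 1.66-fold, PFKM 1.29-fold and PDK1 1.23-fold, and HK1 rose 1.25-fold. Without BIX01294 replicate 3, 3 of these rose, and PDK1 lost its call without DMSO replicate 1 or 2.

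**Figure D3:**
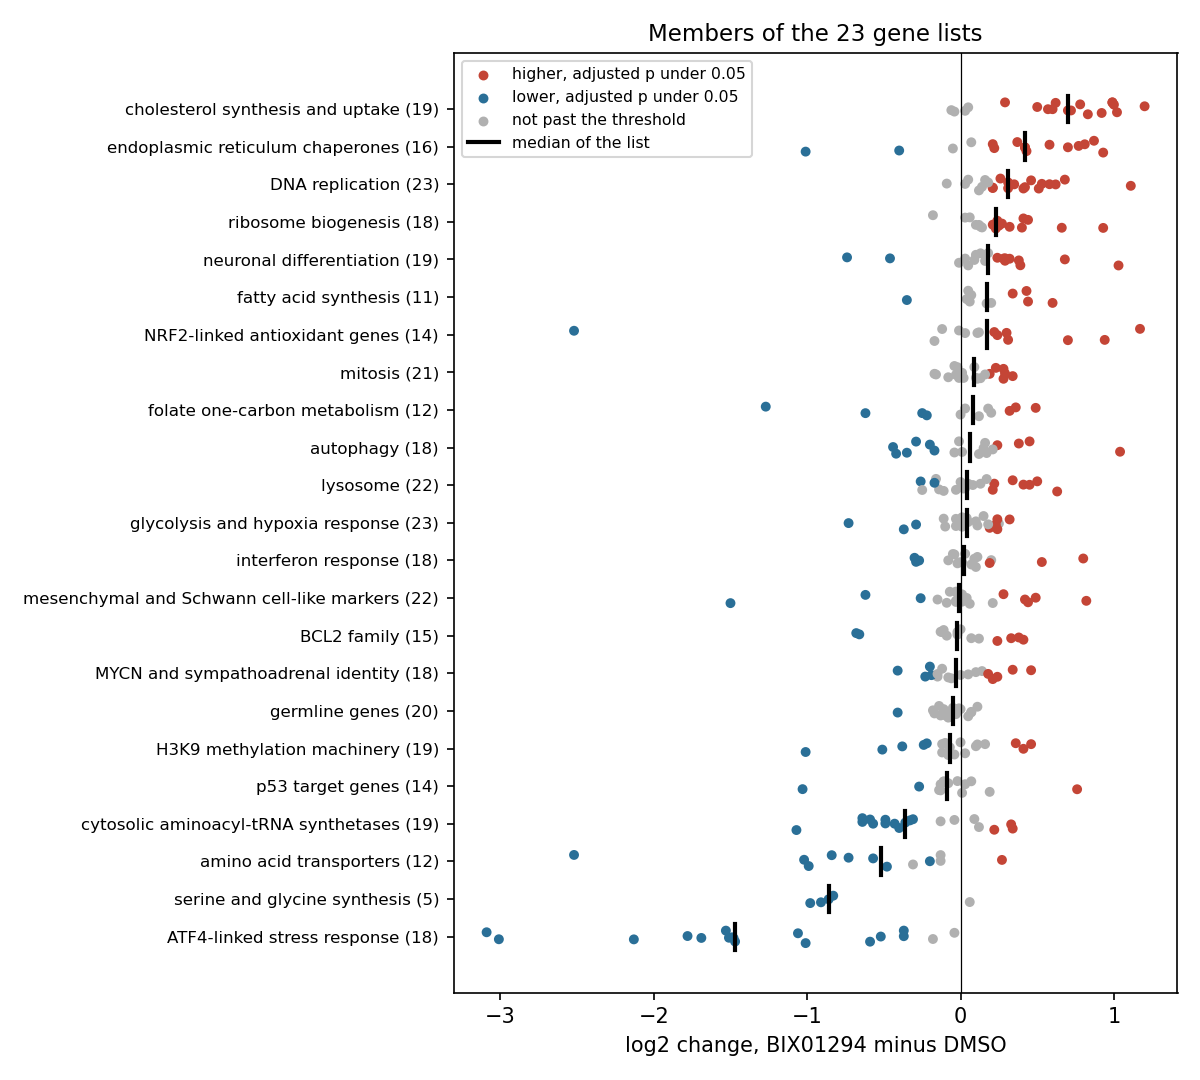
Each point is the log2 change (BIX01294 minus DMSO, horizontal axis) of 1 measured member of the gene list named at the left, with the number measured in brackets; the black bar is the list's median and colours mark members past an adjusted p of 0.05 over all genes. The medians run from -1.47 for the ATF4-linked list to 0.70 for the cholesterol list.

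With the preset correlation 11 of the 23 lists passed camera, 7 higher and 4 lower, and with an estimated correlation none did. Fry, which compares a list with no other genes, called 12 lists. These included lysosome and mitosis, which did not pass camera, but not the NRF2-linked list. The other 9 splits of the 6 arrays into groups of 3 gave between 2 and 10 lists at the preset correlation. Each of these splits held both treatments in unequal numbers on each side. Part of the treatment difference therefore remained, and these counts are not a chance level.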

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

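The tests in this part were chosen after the result was seen, except that of heat shock genes. Rows outside the comparison also held differences from the control arrays: 885 of the 11775 rows with no gene symbol passed an adjusted p of 0.05 in a limma fit over all rows (516 higher, 369 lower, 47 at least 2-fold), and 165 of the 1388 rows with several symbols did (75 higher, 90 lower, 5 at least 2-fold). None of these rows was named.

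The ATF4-linked list fell, with per-array medians of -1.37, -1.31 and -1.50 in the BIX01294 arrays. A level-dependent shift left by the normalization is argued against by the list's median of -1.47, far below the lower limit of -0.10 for matched random lists. Less ATF4 mRNA stays open, because the brighter row fell by 0.52 and the other did not pass the test. Fewer cells or less depleted medium in the treated dishes also stays open, because the glycolysis and hypoxia list had a median of 0.04 with members moving both ways, which decides nothing. An effect of the inhibited enzymes on this programme, or of the compound apart from them, is a further possibility that these arrays could not separate.

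The 7 MT1 and MT2A genes measured rose, while MT3, another metallothionein, differed by -0.09 and did not pass the test (adjusted p 0.627 in limma). Probes shared among the 7 genes cannot be told apart from separate rises: their log2 changes span a range of 2.55, from 0.58 to 3.13, but background may spread the changes of 1 shared transcript in the same way. For a general heat shock response, the median over 10 heat shock genes was 0.28, with an SD of 0.06 between BIX01294 arrays. That lay below the 0.5 set before the result was seen. Still, 7 of the 10 rose and none fell, led by HSPH1 (1.02) and DNAJB1 (0.63). Because the 0.5 is not tied to the size of the metallothionein rises, such a response stays open. A zinc-like signal through the metal-sensing factor MTF1 stays open: the zinc exporter SLC30A1 rose by 1.18, but this was known when it was chosen, the zinc importer SLC39A10 fell by 0.24, and HMOX1 differed by 0.11 and did not pass the test (adjusted p 0.255 in limma).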

How the results depend on the processing

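The count of changed genes ran from 3641 to 5324 over the alternatives to scaling, filter, rows and model. With 1 array left out it ran from 3018 to 3663. Genes changed at least 2-fold ran from 78 to 110, and from 103 to 111 with 1 array left out. Limma's treat, which tests against a log2 change of 0.5 and so counts a different quantity, called 145 genes. The replicate block gave 3641 genes, 3531 of them shared with the fit without it, and 110 at least 2-fold; same-numbered arrays deviated together with correlations of 0.19, -0.18 and 0.05, so the numbers were not taken as pairs, not every array correlated best with its own number, and the block changed no call of a list or named gene. The 99 genes named by rule besides EHMT1 and EHMT2 kept their direction wherever tested (92 and 95 of them under the dim-gene filters), and over genes and alternatives 1360 comparisons stayed on their side of the threshold and 15 calls were lost, for UHRF1 with the mean of rows and for TEX15, IFIT1, KIF23, CCNB1 and PDK1 with 1 array left out. EHMT2 did not pass anywhere but changed sign, at -0.02 under quantile normalization, -0.01 with array weights and between -0.04 and 0.02 with 1 array left out. With an estimated correlation the 11 list calls were lost, with adjusted p of 0.142 (ATF4-linked), 0.163 (cholesterol; transporters), 0.172 (serine), 0.211 (chaperones; replication), 0.266 (neuronal), 0.318 (synthetases), 0.374 (ribosome biogenesis), 0.454 (fatty acid) and 0.680 (NRF2-linked) on 4 residual degrees of freedom. The NRF2-linked call was also lost under quantile normalization (0.05196), array weights (0.0565), with the dimmest genes left out (0.0742 for the smaller filter, 0.4362 for the filter at the median) and without DMSO replicate 3 or BIX01294 replicate 1 (0.0227 to 0.0875 over all arrays left out in turn, the other 4 keeping it), and the fatty acid call with the filter at the median (0.07355). Fry, which asks whether a list's genes move one way on balance and compares them with no other genes, gave 0.114 for the NRF2-linked list, 0.0289 for lysosome and 0.0422 for mitosis, so it does not answer the same question as camera. Mitosis in camera ran from 0.0289 to 0.231 with 1 array left out. Some lists that did not pass changed direction, still without passing, in at least 1 of the fits named, with ranges over all arrays left out: folate under quantile normalization (0.9955), with fry (0.118) and with 1 array left out (0.738 to 0.980); BCL2 with the filter at the median (0.941), with fry (0.912) and with 1 array left out (0.762 to 0.983); sympathoadrenal with fry (0.849) and with 1 array left out (0.892 to 0.983); and with the filter at the median autophagy (0.914), p53 (0.941) and mesenchymal (0.941). The cause of these changes was not tested. The share of changed genes that were higher was 54.7% as deposited, 49.7% after quantile normalization and 64.3% after centring, and the median log2 change of all genes stayed between -0.009 and 0.027 under these scalings. With 3 arrays per group, 68.5% of simulated changes of 0.5 were recovered, with 200 changed genes and independent noise, a setting unlike the real data. Linear-scale pseudocounts were not run, since the values are logarithms.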

Other observations

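The tests and gene groups in this part were chosen after the data were seen, except the counts over other splits. A test of shared zinc finger probes was planned but not run. Many zinc finger genes of chromosome 19, a set in which many encode KRAB repressors, were lower. Of 226 ZNF and ZFP genes measured there, 120 fell, 2 rose and 104 did not pass the test, with a median log2 change of -0.27. The log2 change was -1.21 for ZNF610, -1.19 for ZNF528, -1.13 for ZNF135 and -1.11 for ZNF347 (highest adjusted p 0.000314 in limma). ZNF610 and ZNF347 were dim, with mean levels of 5.96 and 5.63 over the 6 arrays against lower quartiles of 5.36 to 5.41. Their lower levels were not shown to be above background. Of 230 ZNF and ZFP genes on other chromosomes, 37 fell and 14 rose, with a median of -0.04. Of the 1082 other genes of chromosome 19, 146 fell and 57 rose, with a median of -0.05, below the range of -0.02 to 0 of matched random lists. No list test is given for the zinc finger group, which was chosen because its genes fell.

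A group of genes linked to FOXO transcription factors in the literature, of which 5 had been seen before the group was written, held 12 falls and 4 rises among 20, with a median of -0.35, which those 5 partly set. The 5 seen beforehand were KLHL24 (-1.72), PDCD4 (-1.71), YPEL2 (-1.55), CCNG2 (-1.45) and HBP1 (-1.34). BCL2L11 and SESN1 had been named from lists fixed beforehand. The other 13 had a median of -0.09, and 5 of them fell, among them TXNIP (-1.17) and SESN3 (-0.77), and 4 rose, among them KLF6 (0.71). In the metal-responsive group of 11 genes, 8 rose and 1 fell, with a median of 1.06. The 6 not seen beforehand had a median of 0.35, with 3 rises (MT1E, MT1H and MT1M) and 1 fall, and MT3 and HMOX1 did not pass the test.

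For the chromosome 19 zinc finger genes, the median of -0.27 lay outside the range of -0.04 to 0.01 of matched random lists. The gap exceeded the spread between arrays (SD 0.06 in DMSO). The group was chosen because its genes fell, so its place among random lists was set by that choice and decides nothing. With all genes split by level into 10 groups, the median log2 changes ran from -0.052 to 0.073. A level-dependent shift left by the normalization would move all genes of a level, so these medians argue against it as the whole cause. The other genes of chromosome 19 had a median of -0.05, nearer 0 by more than the spread between arrays. They too were lower than matched lists. These values argue against a shift of the whole chromosome by as much as the zinc finger genes fell. ZNF and ZFP genes elsewhere had a median of -0.04, a difference of medians of -0.23. The median of -0.04 lay at percentile 4.95 of matched random lists, at the lower edge of their range of -0.04 to 0.01. It argues against an equal fall of zinc finger genes on every chromosome. Choosing the group for its fall may have widened both gaps, so neither gap measures how far the group stood apart. Probes shared by related zinc finger genes stay open for all 226 genes, since probe sequences were not used here. No biological explanation was tested, and the medians were -0.24 to -0.28 under the scalings tried.

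For the counts of changed genes, 1 of the 10 splits of the 6 arrays into groups of 3 gave as many genes, the real one with 4349, and limma called 0 in each of the others, where 219 to 956 genes had an unadjusted p under 0.05. The count of 110 genes changed at least 2-fold was likewise reached by 1 split, with 0 as the highest other. For the gene lists, the real split gave 11 and the highest other 10. With 10 splits no share under 0.05 can be reached. The other splits also mixed both treatments in unequal numbers on each side. Part of the treatment difference then lay between the sides and part within them, so their counts of genes and lists are not a chance level.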
